A study of Capra hircus with 4 samples.

How the data were processed

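Endometrium, the inner lining of the uterus, was collected from Xinong Saanen dairy goats at gestational day 5, called pre-receptive, and at gestational day 15, called receptive. Per the labels, there were 4 RNA libraries, 2 for each stage. They were depleted of ribosomal RNA, strand-specific and sequenced from both ends. The sample information gives 20 goats of 24 months of age, 10 for each stage. The labels do not state whether a library came from 1 goat or from a pool, so a spread between libraries may be biological or technical. Per the submitters' processing notes, TopHat, TopHat2, Cufflinks and Cuffdiff were used, with no version or role given. The genome build is not given in the sources used here.

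The deposited tables held assembled long non-coding RNA (lncRNA) transcripts with their positions and class codes, the authors' own comparison, predicted cis targets and enrichment tests. CPC and CNCI scores, which measure coding potential, are the authors' values per transcript, per the file headers. The log2 fold change is the authors' deposited ratio of a set of libraries called T over a set called C, and it is infinite where one set is listed at 0. The p-value and q-value of each lncRNA are those of the authors' comparison, per the file headers. The p-value of each GO term, KEGG pathway and target transcript was also deposited by the authors. The title of the comparison names receptive and pre-receptive endometrium, but no label or header used here says which letter is which stage. Directions are therefore given as set T against set C, and none is assigned to a stage. The numbers of lncRNAs per GO term were taken from the deposited table, in which each number equalled the distinct lncRNAs listed for the term in 744 of 744 terms.

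The columns named for single libraries (4) and the columns of set means (2) matched no sample label and no labelled group, and apart from a first look at their values they were not used in any step. The tests planned on values per library were therefore not run, although the names carry the letters T and C: the limma fit with its gene list tests, the counts of stage-restricted lncRNAs, the lncRNAs of highest mean value, and the separation of the replicates. With 2 libraries against 2, an exact permutation test could not have given a p below 0.333. Depth per library is unknown here, because the columns used hold no counts. As those columns were left out, no error between replicates was computed for any fold change, and intervals printed for shares cover counting error only.

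A call is a lncRNA in the authors' deposited table of differential lncRNAs. Pairs of a lncRNA and a target transcript were joined to the target's deposited direction and p. Gaps between a lncRNA and its target were computed from the deposited positions, because the deposited distance class of 100 kb also held pairs as close as 119 bp. Lists of genes were fixed before the data were examined and matched by symbol. Of 386 target gene identifiers, 353 were found in a RefSeq gene table of the ARS1.2 assembly, which was used for names only and gave a symbol to 17 genes that had only a LOC number. A locus group joins all lncRNAs and target genes that are linked by any pair. A run is a set of successive calls with gaps of at most 100 kb.

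Tests were Fisher's exact test (two-sided), the exact binomial test (two-sided), the hypergeometric test (one-sided) for GO terms, and permutation tests (one-sided) with 100000 resamples, with Benjamini-Hochberg adjustment at 0.05. Intervals are 95% Wilson intervals. Transcripts, pairs, neighbouring calls and locus groups are not independent replicates, so these tests describe the deposited lists and not the variation among goats. The planned rank correlation of lncRNA and target changes was not run, because only the direction of the target was used. On simulated data, the GO step on 700 terms recovered 39 of 40 planted terms and called 1 other. Planted terms had an 8-fold expected number with 3 more lncRNAs added, so they were stronger than 8-fold. Simulated lncRNAs were drawn independently, which leaves out several lncRNAs sharing a target gene. For 700 simulated calls with random directions, the neighbour test gave a p under 0.05 in 3 of 40 runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

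The named lncRNAs were chosen by a rule fixed before the data were examined: up to 12 per direction that passed the planned test, filled up with the calls of smallest p. As that test was not run, all were taken by the authors' p, and ties were ordered by the size of the change. The rule also named up to 4 members of each gene list that were targets. Other target genes named in the text were chosen after their values were seen, and a single target gene is counted in the totals but not reported here by itself. The alternatives planned and run were the nearest target of each lncRNA, terms with at least 5 lncRNAs, and Bonferroni adjustment. Other alternatives were added after seeing the data: stricter thresholds, calls above 0 in both sets, a single class, transcript or call per unit, subsets of pairs, and GO terms counted by locus group. Target p values were first adjusted over those under 1, and the adjustment over all target transcripts with a direction, used in the text, was added after that result was seen. A count of GO terms by target gene was also tried and is not reported, because the background counts lncRNAs and some terms then exceeded it.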

Results

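The data describe lncRNA transcripts in goat endometrium at 2 stages of early pregnancy, gestational day 5 (2 libraries) and gestational day 15 (2 libraries). The table of all lncRNAs held 226416 transcripts on 31 chromosomes. Intergenic transcripts made up 98.3% of them. Every transcript in this table of lncRNAs scored below 0, with a highest CPC score of -1 and a highest CNCI score of -0.00041. The scores may have served to select the table, so they are no separate evidence that the transcripts are non-coding. The depth of the libraries is unknown here. Positions are those of the deposited tables, whose genome build is not given in the sources used here.

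The comparison of receptive with pre-receptive endometrium asks which lncRNAs differ between the stages. In the authors' deposited table it is expressed as set T against set C. Among the lncRNAs listed higher in T, several of those with the smallest p lay beside MME, which encodes the membrane metallopeptidase neprilysin, or LOC102183425. TCONS_00024587 (chromosome 1, 110326654 to 110327789) and TCONS_00024606 (chromosome 1, 110389187 to 110391014), both with MME as predicted target, were listed at 0 in C, with p = 5e-05 and q = 0.0365 in the authors' deposited table. TCONS_00059488 and TCONS_00059491, at 18491954 to 18493211 and 18497257 to 18501357 on chromosome 11, had LOC102183425 as predicted target and the same p and q in the authors' deposited table, and were also listed at 0 in C. TCONS_00312923 (chromosome 29, 27814431 to 27815682), beside the DNA damage checkpoint kinase gene CHEK1 and EI24 and STT3A, was likewise listed at 0 in C, with q = 0.0365 in the authors' deposited table. The genes' own transcripts of smallest p were listed lower for MME, CHEK1 and STT3A, with p = 0.235, 0.496 and 0.123 in the authors' deposited table. TCONS_00216353, on chromosome 20 at 28639597 to 28643295, was 14.4-fold higher in T (log2 change 3.84, q = 0.0365 in the authors' deposited table).

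The other lncRNAs named among the higher ones were TCONS_00202915 on chromosome 2, TCONS_00221197 on chromosome 20, TCONS_00262301 on chromosome 24 and TCONS_00362359 on chromosome 4, all without a predicted target and listed at 0 in C. TCONS_00383442, beside the circadian clock repressor gene CRY1, had q = 0.0833 in the authors' deposited table and did not pass 0.05. TCONS_00262112, beside POM121L2, PRSS16 and ZNF391, had q = 0.101 in the authors' deposited table and did not pass either. Both were listed at 0 in C.

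Among the lncRNAs listed lower in T, 2 passed a q of 0.05 in the authors' deposited table. TCONS_00398292 (chromosome 6, 113850904 to 113852127), with IDUA, DGKQ, SLC26A1 and TMEM175 among its predicted targets, was 10.5-fold lower (log2 change -3.39, q = 0.0365 in the authors' deposited table). TCONS_00183980 (chromosome 19, 17856467 to 17860553), beside RAB11FIP4, whose product binds the recycling endosome GTPase Rab11, was 8.48-fold lower (log2 change -3.08, q = 0.0365 in the authors' deposited table). TCONS_00449991 beside the hedgehog receptor gene PTCH1 had a log2 change of -2.70 and q = 0.118 in the authors' deposited table. For TCONS_00084251 and TCONS_00084250, beside the centrosomal protein gene NINL, the authors' deposited table gave log2 changes of -2.97 and -2.83, with q = 0.184 and 0.249. TCONS_00181755, with PRPSAP1 and 4 other predicted target genes, had a log2 change of -2.88 and q = 0.288 in the authors' deposited table. TCONS_00439055 on chromosome 8 had a log2 change of -3.40 and q = 0.173 in the authors' deposited table. The remaining lncRNAs named, TCONS_00047527, TCONS_00241435, TCONS_00242658, TCONS_00238236 and TCONS_00389372, were listed at 0 in T and did not pass.

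The authors' deposited table called 668 lncRNAs, of which 401 were higher in T and 267 lower. The higher share was 60.0% (95% Wilson interval 56.3 to 63.7, exact binomial p = 2.4e-07). All calls had a p of at most 0.0499, whereas q ranged from 0.0365 to 0.894 with a median of 0.551, and 12 calls, 10 higher and 2 lower, had a q under 0.05 in the authors' deposited table. The higher and lower calls differed in kind. Of the 401 higher calls, 354 (88.3%) were listed at 0 in C, against 30 of 267 lower calls (11.2%) listed at 0 in T (Fisher's exact p = 1.1e-95). Where both sets were above 0, 47 calls were higher, with a median log2 change of 3.01 (8.05-fold), and 237 were lower, with a median of -1.94 (3.84-fold), from the authors' deposited table. The majority thus turned, to 16.5% higher, when calls listed at 0 were left out. The columns named for single libraries were looked at when the tables were first read, and then left out because their names match no sample label. In that look, 1 column with T in its name had far fewer values at 0 than the other 3. The calls listed at 0 in C, and with them the split of 401 to 267, can therefore depend on 1 library, and no test of this was made here.

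**Figure D1:**
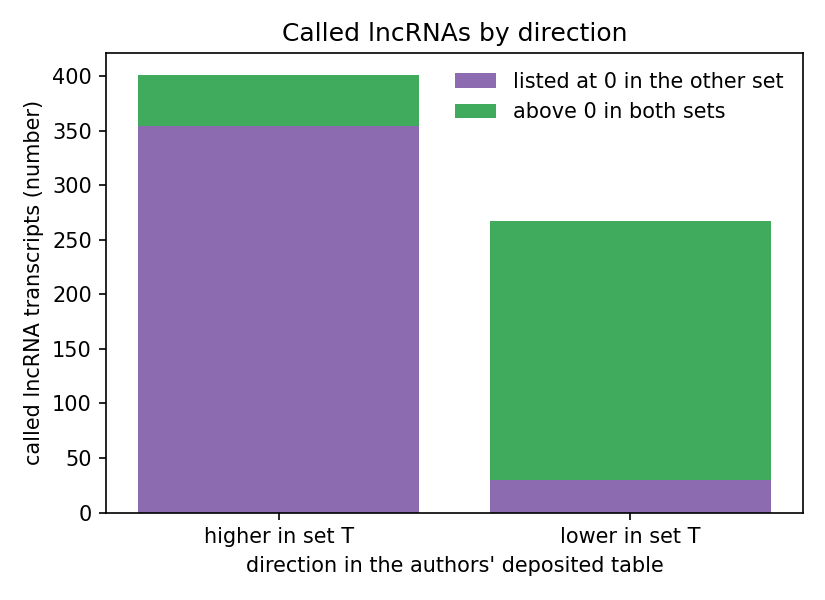
Number of called lncRNA transcripts (vertical axis) that were higher or lower in set T, split into those listed at 0 in the other set and those above 0 in both. Of the 401 higher calls, 354 were listed at 0 in set C, and of the 267 lower calls, 30 were listed at 0 in set T.

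The second comparison asks whether called lncRNAs and the protein-coding genes near them differ in the same direction. Beside here means a predicted cis target in the deposited distance classes of 1, 10 or 100 kb, with 53, 200 and 756 pairs. Lower lncRNAs lay beside lower transcripts of ANPEP (aminopeptidase N), NINL, PRPSAP1 and DDT, and beside transcripts of DSG2 (a desmosomal cadherin) and CCNB1 (cyclin B1) that were listed lower. The lncRNA of DDT, TCONS_00155184 (q = 0.457), ended at 70432351 on chromosome 17, and the DDT locus began at 70471852. It was also paired with other lower target transcripts of p = 5e-05 in the authors' deposited table. Higher lncRNAs lay beside transcripts listed higher of CRIM1, a transmembrane protein that binds bone morphogenetic proteins, of EMB (embigin), of BCL2L15, a member of the BCL2 family, and of GPR37. Adjusted p values of targets are Benjamini-Hochberg values computed here over all 816 target transcripts with a direction, and DSG2 (0.15), CCNB1 (0.148), CRIM1 (0.148), EMB (0.512) and GPR37 (0.857) did not pass. For a gene with several target transcripts, the values are those of the transcript of smallest p, and no other transcript of that gene had p under 0.05. For ANPEP (gene 102185784, chromosome 21, 19131116 to 19147778) the authors' deposited table gave p = 5e-05 (adjusted p = 0.00583), and its 3 lncRNAs had log2 changes of -3.03, -1.94 and -1.87. The 3 lncRNAs beside NINL (gene 102171167, chromosome 13, 10140135 to 10200004) had log2 changes of -2.97, -2.83 and -1.90 in the authors' deposited table, with p = 5e-05 for the target. CRIM1 (gene 102183697, chromosome 11, 18613992 to 18793639) had p = 0.002 (adjusted p = 0.148, or 0.0485 over the 267 target transcripts with a p under 1), and its lncRNAs TCONS_00049365 and TCONS_00049366 had log2 changes of 2.28 and 2.57 in the authors' deposited table. EMB had p = 0.0156 for 1 of its 9 target transcripts, with log2 changes of 2.64 and 2.70 for its 2 lncRNAs in the authors' deposited table. None of the lncRNAs given here for ANPEP, NINL, CRIM1 and EMB had a q under 0.05. Their q ran from 0.184 at NINL to 0.894 at ANPEP in the authors' deposited table. Calls with q = 0.0365 did lie in the same runs. TCONS_00216353, without a predicted target, was in the EMB run. TCONS_00059488 and TCONS_00059491, with LOC102183425 as predicted target, were in the CRIM1 run. Beside TCONS_00183980 (q = 0.0365), RAB11FIP4 had a transcript listed lower, with p = 0.00275 in the authors' deposited table (adjusted p = 0.173, not passed).

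Predicted cis targets were given for 255 of the 668 calls (38.2%), in 1009 pairs with 880 transcripts of 387 genes. Of these genes, 1 had no identifier and held a date in place of its symbol. A target was given for 47.9% of the lower calls and 31.7% of the higher calls (Fisher's exact p = 3.2e-05). A direction was given for 816 target transcripts, and 549 of these had a p of 1, which the headers used here do not explain, so it is open whether these were tested. A p under 0.05 was listed for 36 transcripts of 36 genes, 4 higher and 32 lower. An adjusted p of 0.05 was passed by 8, 1 higher and 7 lower, and by 12 when only the 267 with a p under 1 were adjusted, a set chosen by the p itself. Over all 929 pairs with a direction, lncRNA and target went the same way in 575 (61.9%, 95% Wilson interval 58.7 to 65.0), against 50.6% from the totals (Fisher's exact p = 1.2e-13). With targets of a p of 1 left out, 206 of 312 pairs did (66.0%), against 55.0% from the totals (Fisher's exact p = 1.3e-07). Among the 50 pairs whose target had p under 0.05, 47 went the same way (94.0%, interval 83.8 to 97.9), 41 both lower and 6 both higher, against 74.3% from the totals (Fisher's exact p = 5.3e-06). The 3 exceptions were lncRNAs listed at 0 in C beside transcripts listed lower of TNFRSF10B, RBBP7 and LOC102183306. With 1 pair per locus group, that of smallest target p, 25 of 28 went the same way, against 67.9% from the totals (Fisher's exact p = 0.0017). Of these 25, 21 were both lower. The share was 76.4% (62.9% from the totals) for pairs whose lncRNA was above 0 in both sets, and 42.8% (41.1% from the totals, Fisher's exact p = 0.40) for pairs whose lncRNA was listed at 0 in one set, most of them in C. Beside higher lncRNAs listed at 0 in C, 126 of 334 targets were listed higher (37.7%), against 67 of 115 (58.3%) beside higher lncRNAs above 0 in both sets (Fisher's exact p = 0.00019). With 1 pair per locus group it was 24 of 71 against 12 of 18 (Fisher's exact p = 0.0156). With targets of a p of 1 left out, it was 22 of 104 (21.2%) against 17 of 29 (58.6%, Fisher's exact p = 0.00019).

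**Figure D2:**
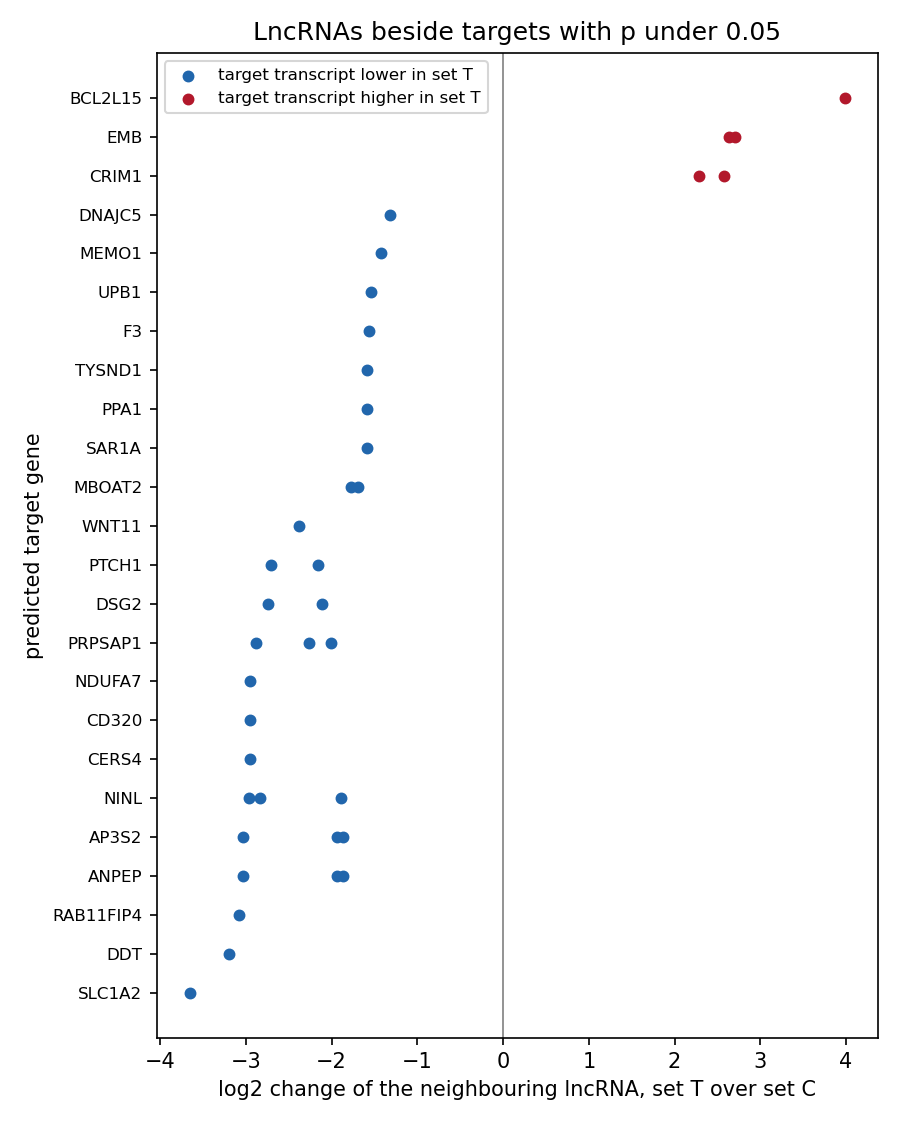
Each point is a called lncRNA beside a target transcript with p under 0.05, by its log2 change from set C to set T (horizontal axis) and its target gene (vertical axis), coloured by the direction of the target. Targets with a symbol in the deposited table are drawn. LncRNAs listed at 0 in one set have no finite change and are not drawn, and every drawn pair goes the same way.

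Of the gene lists fixed for endometrium, endometrial gland secretion and conceptus elongation had the most members among the targets. PTCH1 had 2 lower lncRNAs, WNT11 had 1 lower lncRNA (log2 change -2.38, p = 0.0243 in the authors' deposited table), and the glucose transporter gene SLC2A1 had 1 lncRNA listed at 0 in C (p = 0.00055 in the authors' deposited table). The target transcripts of PTCH1 and WNT11 were listed lower, with p = 0.0157 and 0.0137 (adjusted p = 0.512 and 0.506, not passed), and that of SLC2A1 had p = 1 in the authors' deposited table. From the cell cycle list, CCNB1 had a transcript listed lower (p = 0.00195, adjusted p = 0.148, not passed, or 0.0485 over those with a p under 1) beside a lncRNA listed at 0 in T (p = 0.0495 in the authors' deposited table). TNFAIP3, an inhibitor of NF-kappa-B signalling from the list of complement and innate immunity, and MS4A1, the B cell marker CD20 from the list of blood and leukocytes, each lay beside 1 higher lncRNA. The smallest p of their own transcripts was 0.18 and 1 in the authors' deposited table. None of the lncRNAs beside these list members had a q under 0.05 there. The q was 0.69 for the lncRNA of WNT11, 0.191 for SLC2A1, 0.894 for CCNB1, 0.721 for TNFAIP3 and 0.894 for MS4A1.

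The lists held too few lncRNAs for the test of direction against the other called lncRNAs with a target. Whatever the directions, the smallest p any list could have given was 0.0601, so none could pass. Endometrial gland secretion had 1 higher and 3 lower lncRNAs, against 126 and 125 among the rest (Fisher's exact p = 0.622, adjusted p = 0.829). Cell cycle, complement and innate immunity, and blood and leukocytes had 1 lncRNA each. The other 12 of the 16 lists had 0 members among the targets: interferon response, steroid hormone receptors, prostaglandin and oxytocin, cell adhesion and extracellular matrix, growth factors and morphogens, homeobox and developmental factors, known non-coding RNAs, trophoblast, smooth muscle, endothelium, epithelium and stroma. In all, 6 of the 521 list genes were targets. A gene can be a target only if a called lncRNA lies near it, so these counts do not measure the expression of the lists.

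Peptidase genes, the riboflavin transporter gene SLC52A3 and PRPSAP1, whose product associates with phosphoribosyl pyrophosphate synthetase, were among the targets behind the enriched terms. The renin-angiotensin system was the 1 KEGG pathway of 146 that passed adjustment (p = 1.1e-05 in the authors' deposited table, adjusted p = 0.00162), through 6 lncRNAs beside 2 genes, the peptidases MME and ANPEP. LncRNAs beside MME were listed higher and those beside ANPEP lower. The MME transcript of smallest p was itself listed lower, with p = 0.235 in the authors' deposited table, and that of ANPEP lower with p = 5e-05. Metallopeptidase activity had 6 lncRNAs, beside ANPEP, CNDP2, MYSM1 and RNPEPL1 (adjusted exact hypergeometric p = 0.0163). Riboflavin transporter activity, with 3 lncRNAs beside SLC52A3, had the smallest p of the GO terms (adjusted exact hypergeometric p = 0.0073), and nucleotide biosynthetic process had 3 lncRNAs beside PRPSAP1 (adjusted exact hypergeometric p = 0.0126). Spindle had 7 lncRNAs beside 5 genes, among them RCC2 and MID1 (adjusted exact hypergeometric p = 0.0302).

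Of 744 GO terms, 153 had a p under 0.05 in the authors' deposited table, and 20 passed adjustment. The deposited numbers count lncRNAs and not genes, and 14 of the 20 terms rested on 1 gene in 1 locus group. With each locus group counted once, 0 terms passed in the hypergeometric test, and 127 had an unadjusted p under 0.05. The background still counted lncRNAs and was not grouped, which raises p for a term resting on 1 locus group. For riboflavin transporter activity, the unadjusted hypergeometric p went from 9.8e-06 to 0.0362. The count of 0 therefore does not show that no term is enriched.

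Called lncRNAs also lay in runs along the chromosomes, most of them lower in T. The longest run held 13 lower calls on chromosome 29 (9539384 to 10091965), and a further 7 lower calls lay at 10259844 to 10446226, with DLG2, a synaptic scaffold gene, among the targets. On chromosome 13, 8 lower calls lay at 23369745 to 23573292 and 7 at 23678546 to 23759623, and on chromosome 25 there were 7 at 30703049 to 30940903. Runs of higher calls lay near CRIM1 (6 calls, chromosome 11, 18491954 to 18611092), MME (4 calls, chromosome 1, 110230358 to 110405339) and EMB (3 calls, chromosome 20, 28578578 to 28643295). Of 24 runs with at least 3 calls, 18 were all lower, 5 all higher and 1 mixed. Neighbouring calls within 100 kb went the same way in 96.3% of 134 pairs, against 52.0% with shuffled directions (permutation p = 1e-05, the smallest the test can give). Of the lower calls, 146 of 267 had another within 100 kb, against a mean of 7.72 in random draws from all transcripts (permutation p = 1e-05). Of the calls listed at 0 in C, 22 of 354 did, against 13.5 (permutation p = 0.0711). The draws were not matched on expression level.

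**Figure D3:**
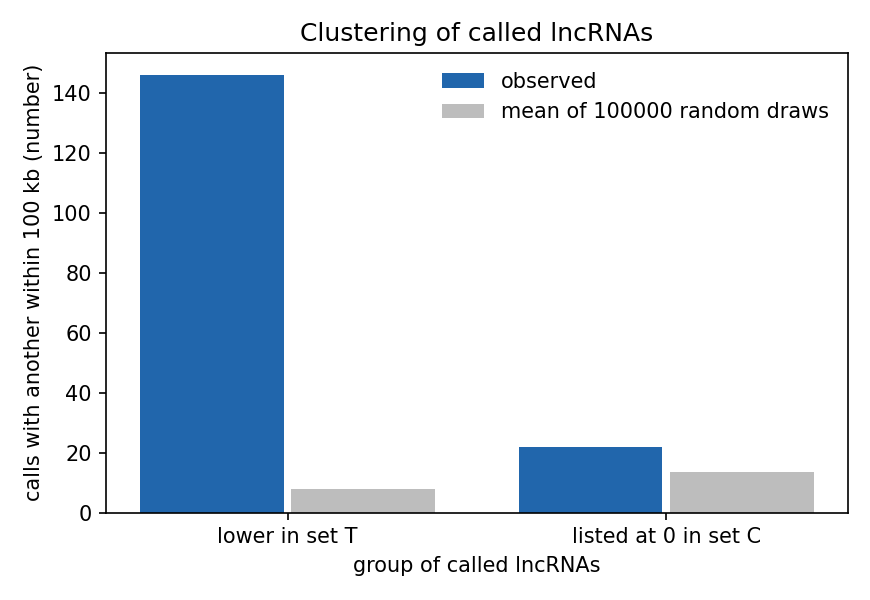
Number of called lncRNAs with another call of the same group within 100 kb (vertical axis), for calls lower in set T and calls listed at 0 in set C, observed and as the mean of 100000 random draws from all transcripts. Of the lower calls, 146 had such a neighbour against 7.72 in the draws, and of the calls listed at 0 in C, 22 against 13.5.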

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

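Every alternative given here was chosen after seeing the data, except the nearest target of each lncRNA, terms with at least 5 lncRNAs and Bonferroni adjustment. The split of calls depended on the threshold: 10 higher and 2 lower (83.3% higher) at q under 0.05, and 195 and 68 (74.1%) at p under 0.01, where 182 calls were listed at 0 in C. With both sets above 0, 47 calls were higher and the majority reversed, to 16.5% higher, because calls listed at 0 were mostly higher ones. With 1 call per run of neighbours, 161 lower calls were left and 69.9% were higher, because lower calls lay in runs. Intergenic calls alone and 1 transcript per assembled gene kept the split, at 60.4% and 60.0% higher. LncRNA and target went the same way beyond their totals in 9 of 11 alternatives, from 62.2% to 94.0%, among them the higher lncRNAs listed at 0 in C pooled with every lower lncRNA (62.4%, 54.0% from the totals), where 382 of the 508 agreeing pairs were lower ones. They did not pass Fisher's exact test for lncRNAs listed at 0 in either set (42.8%, and 33.3% with targets of a p of 1 left out), and the cause was not tested. Of the subsets by distance, only the pairs in the deposited classes of 1 and 10 kb are counted among these 11 (67.8%, 50.4% from the totals). The other subsets by distance are not counted. Pairs with a gap over 10 kb, given under other observations, did not pass with 1 pair per locus group. GO terms past adjustment numbered 9 among terms with at least 5 lncRNAs, 3 with Bonferroni and 0 by locus group. The count by locus group kept a background of lncRNAs that was not grouped. The single KEGG pathway passed in both alternatives, but the count by locus group was not run for it, and its 6 lncRNAs lie in 2 locus groups. Of the targets, 8 passed adjustment, or 12 with a p of 1 left out, and no gene list could have passed with the nearest target or a gap within 10 kb, where the smallest p possible was 0.0601 and 0.378. Neighbouring calls went the same way in 97.0% of pairs 10 to 100 kb apart (51.9% with shuffled directions) and 99.1% of pairs above 0 in both sets (72.3% with shuffled directions). The choices fixed beforehand on values per library (pseudocounts, filters, scalings, limma settings, count tools, each replicate left out, presence limits, pairs by mean value and by separated replicates) were left out, because columns that match no sample label or labelled group were not used. No paired analysis was possible because the columns carried no replicate numbers of the labels. Depth limits could not be judged without counts.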

Other observations

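The tests in this part on GO terms by locus group, on pairs over 10 kb apart and on targets of higher lncRNAs were chosen after the result was seen, as were the comparisons of chromosomes and class codes. Chromosome 29 held 36 calls, 8.44 per 1000 transcripts (adjusted Fisher's exact p = 1.0e-06), of which 26 were lower. Chromosome 13 held 33 calls, 5.20 per 1000 (adjusted p = 0.0317), of which 28 were lower. On chromosome 1, in contrast, 35 calls were higher and 3 lower (adjusted p = 0.00015 for direction). With each run counted once, chromosome 29 held 16 (unadjusted Fisher's exact p = 0.0759, adjusted p = 1) and no chromosome passed adjustment for number. For direction, taken from the call of smallest p in each run, none passed either, with 30 higher and 3 lower on chromosome 1 (Fisher's exact p = 0.0054, adjusted p = 0.0837). Transcripts that share a splice junction with a known gene made up 8 of the 668 calls, against 581 of all 226416 (adjusted Fisher's exact p = 0.0015). Transcripts antisense to a known exon made up 2 calls, against 3171 of all (adjusted p = 0.0156).

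The excess of calls listed at 0 in C is open to a technical account, which was formed after the look at the columns of single libraries, where 1 column with T in its name had far fewer values at 0 than the other 3, and before the result of the test here was seen. If signal in the set T were scattered evenly over the genome, such calls would cluster no more than random transcripts, and 22 of 354 had another within 100 kb against a mean of 13.5 in random draws (permutation p = 0.0711). A p above 0.05 does not show that they did not cluster. The lower calls came out otherwise, with 146 of 267 against 7.72. But 237 of them were above 0 in both sets, and the calls listed at 0 in T were not tested apart. This contrast therefore cannot speak to scatter in T. Targets were listed higher less often beside higher lncRNAs listed at 0 in C (37.7%) than beside those above 0 in both sets (58.3%, Fisher's exact p = 0.00019). With targets of a p of 1 left out, the shares were 21.2% and 58.6%. Beside those listed at 0 in C, targets were still listed higher more often than beside lower lncRNAs, with 126 higher and 208 lower against 98 and 382 (Fisher's exact p = 7.7e-08). Without targets of a p of 1, it was 22 and 82 against 12 and 167 (Fisher's exact p = 0.00051). Scattered signal in T may account for part of these calls, and these values do not settle it. Depth, a single library of unusual background and a difference of stage were not tested, because columns that match no sample label were left out.

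Neighbouring calls that go the same way might be pieces of a single transcription unit. If such units reached no further than 10 kb, calls 10 to 100 kb apart would not share a direction, yet 97.0% of 67 such pairs did, against 51.9% with shuffled directions (permutation p = 1e-05, the smallest the test can give). Longer transcription units, and genomic regions regulated together, stay open as hypotheses, and no biological explanation was tested.

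The shared direction of lncRNA and target could arise if lncRNAs were unannotated parts of the target's transcript. Set up before the result was seen, a comparison of the 1 kb class with the other classes used targets of p under 0.05. It held only 2 pairs in the 1 kb class and decided nothing (Fisher's exact p = 1). Nor were the other classes distant sets, with smallest gaps of 56 bp in the 10 kb class and 119 bp in the 100 kb class. At ANPEP, in the 100 kb class, TCONS_00236882 began at 19148009 and the target locus ended at 19147778. Pairs with small measured gaps were not tested apart. Pairs with a gap over 10 kb went the same way in 58.3% of 199, against 50.2% from the totals (Fisher's exact p = 0.00195), but with 1 pair per locus group in 52.7% of 93, against 47.4% (Fisher's exact p = 0.244). Among those with a target p under 0.05 it was 88.0% of 25, against 69.8% (Fisher's exact p = 0.0087), and with 1 pair per locus group 78.6% of 14, against 54.1% (Fisher's exact p = 0.0549). Co-regulation at a distance and unannotated ends of nearby genes cannot be told apart for these pairs, since the link passed over pairs but not over locus groups, and the deposited tables used here give no strand.

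For GO terms, 0 passed adjustment with each locus group counted once, whereas random draws of 172 lncRNAs, the number of locus groups, left a median of 14 terms (range 0 to 27), and 2.3% of 1000 draws left as few. The background counts lncRNAs in both cases, whereas only the count by locus group set grouped units against it. The draws therefore do not match that count, and they do not settle why 0 terms passed.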
